A study of Caenorhabditis elegans with 2 samples.

How the data were processed

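Peak lists were analysed for 2 biological replicates of AMA-1 ChIP-seq from whole L4 larvae, which the labels call separate biological replicates. The notes deposited with the samples give what each list was made from. Each replicate's list was made from that library's alignments and a control as peaks and background for an irreproducible discovery rate (IDR) analysis; a pooled list was made from the alignments of both; and the IDR set was made from both replicates' lists and the pooled list. Each exists for builds ce10 and ce11. The aligner, the peak caller, their versions, any filter on reads and the IDR threshold are not given in the sources used here, and the control was not analysed here. Because peaks were called per library and also on pooled alignments, the replicates could be compared with each other, while the IDR set has no replicate error of its own.

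The deposited score per peak is the signal value from the authors' caller, with no fixed range, and it was used only to rank, describe or filter peaks within a list. The deposited −log10 q-value per peak reached the same maximum at 3767 pooled peaks and at all 2082 IDR peaks on ce11, so it could not rank them. The IDR set on ce11 was found to be exactly the 2082 pooled peaks of highest signal. Of its summits, 67.2% lay within 100 bp of one of replicate 1's 2082 strongest and 60.0% of replicate 2's; 35.0% were matched in both, 57.2% in 1 and 7.78% in neither. In the full lists these shares were 93.0% and 88.3%. Read depth per sample is unknown here, so no limit of detection from reads is given.

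Coordinates, gene models and RNA classes came from Ensembl release 115 for WBcel235, which is the same assembly as ce11; every peak on ce11 ended within the length of its chromosome. No position on ce10 was compared with genes. A gene start is the outermost annotated 5′ end. A gene was counted as having a summit when one lay within 500 bp of its start. Summits were put in the first class that applied of gene start, gene end (both within 500 bp, protein-coding genes), gene body and outside. The central part of a chromosome is the middle one of 3 equal lengths. Coordinates are 1-based.

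The tests, the 41 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists were compared with all other protein-coding genes, and RNA classes with all protein-coding genes, by two-sided Fisher's exact test with Benjamini-Hochberg (BH) adjustment over lists of 5 or more members. Positions were compared with 1000 circular shifts of the peak set within each chromosome, two-sided, whose smallest p is 0.001. Medians of signal were compared by 1000 permutations. Genes are not independent replicates, and neighbours can share a summit. To give a value per replicate, each replicate's list was limited to its 2082 strongest peaks, and the mean and SD are over n = 2. With 1 group of 2 samples no test between groups and no regrouping of samples was possible. Of the heat-inducible genes as written, 2 names found no match of their own, because the annotation gives each of 2 gene pairs 1 name; the list still held 9 genes.

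The genes named are the nearest to the 20 strongest IDR peaks (the nearest start of any gene except piRNA within 500 bp, otherwise the gene holding the summit), up to 3 members of each list with the highest signal at the start, the 10 IDR peaks whose rank percentiles differed most between the replicates, and ama-1. Genes named beyond that rule, including those in the comparison of gene groups between replicates and those with many summits, were chosen after their values were seen. That comparison took for each gene the rank percentile of its best peak within 500 bp of the start among all 30000, 0 if none, and set a list's median difference against 100000 random draws of as many genes from the 7646 with a peak in either replicate, with BH adjustment over 28 lists of 5 or more such genes. It was first run on 10 lists picked by hand and widened to all 28 after those results were seen.

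The alternatives were each replicate's own strongest peaks in place of the IDR set, the 1041 strongest IDR peaks, windows of 250 and 1000 bp, every annotated transcript start, peak intervals or whole genes in place of summits at starts, genes with no other protein-coding start within 1000 bp, the 4164 strongest pooled peaks, other matching rules for replicates, merging of peaks, and ce10. Circular shifts in place of Fisher's exact test for the lists were added after the data were seen.

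The methods were tested on simulated data. In 20 shifted copies of the IDR set, with no list enriched, a mean of 0.3 of the 41 lists was called. Of 1000 random lists of 40 genes, 1.4% fell below an unadjusted p of 0.05 in the real set. When a summit was added at 10% of the genes of such a list, 66.0% of 100 lists were recovered at that unadjusted p, and at 20% all were. A set with 50% of its summits placed at starts gave a gene start share of 59.5% where 59.4% was set. For the comparison of lists between replicates, 5% of 200 random lists of 20 genes fell below 0.05, and 93.5% did with 40 points added. These lists came from the same genes as the random draws, so a share near 5% was built in. Lists of other sizes and lists of neighbouring genes that share a peak were not simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.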

Results

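The series profiled RNA polymerase II on the chromatin of wild-type Caenorhabditis elegans at the last larval stage, L4. Chromatin was immunoprecipitated with an antibody against AMA-1, the large catalytic subunit of RNA polymerase II, from whole animals of both sexes, and sequenced (ChIP-seq). There was 1 group with 2 biological replicates, so no contrast between conditions exists. The questions the design allows are where the polymerase was found, at which genes, and how far the replicates gave the same sites. For each replicate the authors deposited a list of 30000 peaks, and for both together a pooled list of 30000 peaks and a smaller set of 2082 peaks that passed an irreproducible discovery rate filter (IDR set) on genome build ce11. The median peak width was 350 bp in replicate 1, 330 bp in replicate 2 and 344 bp in the pooled list and the IDR set. Exactly that width was held by 99.2%, 99.5%, 99.05% and 87.7% of their peaks, in that order. Widths and covered length therefore do not measure how far the polymerase extended. The IDR set covered 0.679 Mb in 2035 merged regions. Read depth is unknown here, so no value has a counting error from reads, and the intervals given for shares cover the number of peaks or genes only.

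The strongest polymerase peaks lay at small non-coding RNA genes, above all those for SL2 RNA, the leader that is trans-spliced onto messages from downstream genes of operons. The peak of highest signal (897.6) covered sls-2.4 and the overlapping non-coding gene R12E2.18 on chromosome I at 4172047 to 4172528, with its summit in an exon of both. Next came sls-2.2 (signal 873, II: 5543440 to 5543882) and sls-2.1 (798.9, II: 5844704 to 5845155), and these 3 peaks ranked 2, 1 and 3 in replicate 1 and 1, 3 and 4 in replicate 2. The peak over Y75B8A.49 also lay in an exon of sls-2.8 (signal 442.6), and sls-2.3 stood at rank 15 (353.2). Other non-coding genes among the 20 strongest peaks were sup-6, annotated as a small nuclear RNA (603.3, with the summit 192 bp away in an intron of F58G1.7), C30E1.9 on X with a pair of peaks (547.2 and 339.3), F40F9.15 (519), the microRNA gene mir-52 (407.6), tts-1 (374.1), W05H9.3 (361.9), F01D5.14 (338.3) and F38E11.11 (336.2). The summit named for F40F9.15 lay in the 5′ UTR of drap-1.

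Protein-coding genes among the 20 strongest peaks were few. mdt-26, a subunit of the Mediator complex, held a peak of signal 707.1 in a coding exon at II: 5661051 to 5661513 and another of signal 507.1 in an intron at II: 5661609 to 5661999. tos-1 had a summit in its 5′ UTR (530.8, V: 9343908 to 9344332), and taf-4, a subunit of the general factor TFIID, had one 221 bp from its start (324.5, I: 382471 to 382763). The peak nearest the start of kel-3 (412.3, III: 13464391 to 13464918) lay in the 3′ UTR of ant-1.1, a mitochondrial ADP/ATP carrier. The summit of the peak at rank 20 (310.6, II: 8747201 to 8747582) lay in no gene, just beyond the end of mak-1 at 8747250.

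Polymerase summits gathered at the starts and the ends of protein-coding genes. Of the 2082 IDR summits, 972 (46.7%, 95% Wilson interval 44.6 to 48.8) lay within 500 bp of a gene start, against 18.9% ± 0.926 (SD) in 1000 circular shifts of the set along each chromosome, a ratio of 2.47. A further 497 (23.9%, 22.1 to 25.7) lay within 500 bp of a gene end, against 12.2% in the shifts. Summits near both a start and an end were counted as starts, so these shares do not rank starts above ends. Counted by gene without that order, 1198 of 19973 genes had an IDR summit within 500 bp of the end and 1113 within 500 bp of the start. Summits elsewhere in a gene made up 18.2% against 44.4%, and those outside genes 11.3% against 24.5%. In the replicates' own 2082 strongest peaks, the start share was 44.8% ± 7.91 (SD, n = 2), with 39.2% in replicate 1 and 50.4% in replicate 2, and the end share was 23.7% ± 1.66 (SD, n = 2). All 4 classes had a two-sided empirical p of 0.001, adjusted over the 4, the smallest that 1000 shifts can give.

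Around gene ends, the bin from 100 to 199 bp downstream held most summit-gene pairs, 217.1 per 1000 IDR summits, and it held 187.8 and 187.3 in replicates 1 and 2. A summit near several genes was counted once for each of them. Around gene starts, the highest bin was the first 100 bp of the gene (123.4 pairs per 1000 summits), with a second group upstream (87.9 from -200 to -101 bp). At 300 to 399 bp inside the gene there were 10.6 pairs per 1000 summits. Several summits per gene were found in some genes: 159 genes held 2 or more IDR summits anywhere between their start and end. The highest counts were in long genes, mnk-1 with 11 (12624 bp), lin-14 with 8 (20312 bp), and ppfr-1 (25884 bp) and spsb-1 (32993 bp) with 7 each. Overlapping genes can share summits, and no number expected from gene length was computed. hsp-90, a cytosolic chaperone, held 5 within 3628 bp, and icl-1, the glyoxylate cycle enzyme, held 4. These genes were singled out after their values were seen.

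**Figure D1:**
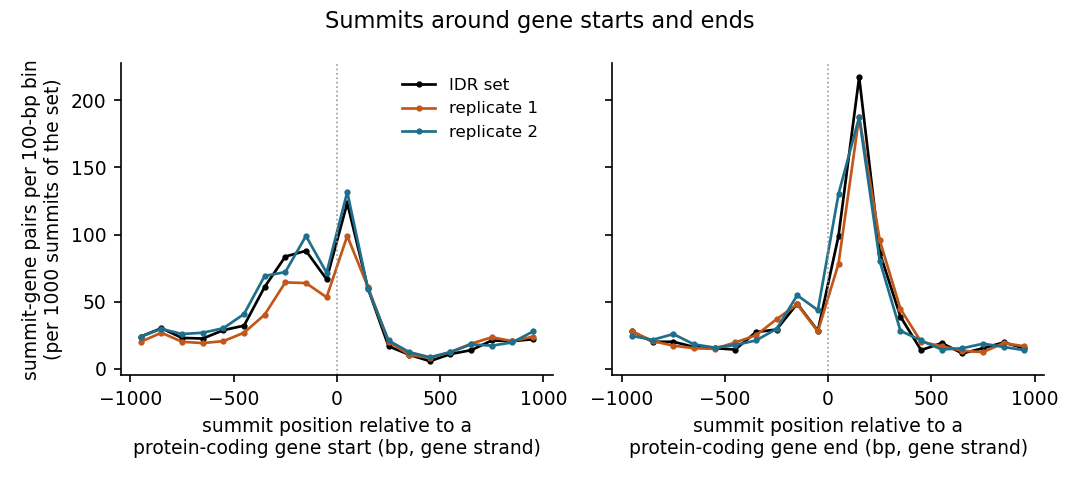
Summit-gene pairs per 100-bp bin (vertical axis, per 1000 summits of the set) against position in bp along the gene's strand, around starts (left) and ends (right) of protein-coding genes, for the IDR set and for each replicate's 2082 strongest peaks. All 3 lines are highest just downstream of the end, at 217.1 per 1000 in the IDR set.

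Peak height differed little between these classes. IDR summits inside gene bodies had a median signal of 58.1 against 63.6 for the rest (permutation p = 0.001, BH-adjusted p = 0.004, two-sided, 1000 permutations of the class labels over peaks). Summits at gene starts had a median of 63.7 against 61.8 (permutation p = 0.047, BH-adjusted p = 0.0939), and those at ends (63.9) and outside genes (62.9) did not differ from the rest either. The gene body difference was present in both replicates' own lists.

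An IDR summit within 500 bp of the start was found for 1113 of 19973 protein-coding genes (5.57%), and genes of protein synthesis and energy metabolism were far above that share. Among ribosomal protein genes 46 of 81 had one (56.8%, 95% Clopper-Pearson interval 45.3 to 67.8), among them rpl-12 (signal 132.5), rpl-35 (131.3) and rpl-20 (127.2). The replicates' own shares were 43.2% ± 1.75 (SD, n = 2). The ribosomal share depended on the window, with 19.8% of genes at 250 bp and 75.3% at 1000 bp. Subunits of the vacuolar ATPase, the proton pump of acidic organelles, had one at 11 of 20 genes (55.0%; vha-2 at 114.9, vha-8 at 110.7, vha-1 at 102.9), and genes of oxidative phosphorylation at 18 of 43 (41.9%; cox-5A at 138.8, cox-5B at 111.1, atp-2 at 107.1). Glycolysis genes followed with 6 of 19 (31.6%), led by aldo-2 (201.7) and gpd-3 (125.6), and translation factors with 6 of 31 (19.4%), led by eef-1G (94.0), eef-1B.1 (91.6) and eef-2 (89.02).

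Genes of protein folding and turnover and of RNA processing were also above the other protein-coding genes. Constitutive chaperones had a summit at 6 of 15 starts (cct-8 at 100.4, hsp-1 at 92.4, hsp-110 at 79.7), splicing factors at 11 of 33 (33.3%; prp-8 at 85.2, prp-40 at 83.3, rsp-6 at 78.3), the proteasome at 8 of 33 (24.2%; rpn-3 at 79.7, pas-1 at 72.9, pbs-3 at 72.5), and the RNA polymerase II machinery at 6 of 36 (16.7%; taf-4, taf-9 and rpb-9). The summit counted for rpn-3 is the same one as for hsp-110, since these genes start on either side of it. That of pbs-3 lay in the 3′ UTR of ulp-2. Cuticle collagens, which are made anew for each larval cuticle, had a summit at 22 of 170 starts (12.9%, interval 8.29 to 18.9), led by col-10 (150.7), col-103 (132.5) and col-94 (105.7). The replicates differed most in 3 of these lists, with 25 genes in replicate 1 and 11 in replicate 2 for collagens, 4 and 13 for the proteasome, and 3 and 9 for the polymerase machinery; splicing factors had 7 and 9.

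Each of these lists was higher than the other protein-coding genes by Fisher's exact test, two-sided, with BH adjustment over 41 lists. The odds ratios of these exact tests ran from 23.2 for ribosomal proteins (adjusted p = 1.81e-35), 20.9 for the vacuolar ATPase (9.47e-09), 12.4 for oxidative phosphorylation (2.58e-11) and 11.4 for chaperones (0.00028) down to 3.40 for the polymerase machinery (0.0259) and 2.55 for collagens (0.000654). The collagen call was lost in replicate 2's own peaks (6.47%, adjusted exact p = 0.847), and those of the proteasome (12.1%, 0.12) and the polymerase machinery (8.33%, 0.341) in replicate 1's. Among genes with no other protein-coding start within 1000 bp, the translation factors (15.4% of 13 genes, adjusted exact p = 0.178), proteasome (20% of 10, 0.126), splicing factors (20% of 10, 0.126) and polymerase machinery (6.25% of 16, 0.652) were no longer called, with far fewer genes tested. Among the 1041 strongest IDR peaks, splicing factors stood at 9.09% (adjusted exact p = 0.134), and the proteasome (0.134) and polymerase machinery (0.151) were not called either. The polymerase machinery was also not called over whole genes. With a window of 250 bp every list called higher here kept its call, but the order of the lists changed. Ribosomal proteins then stood at 19.8% and chaperones at 20%, below the vacuolar ATPase (40%) and oxidative phosphorylation (30.2%).

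**Figure D2:**
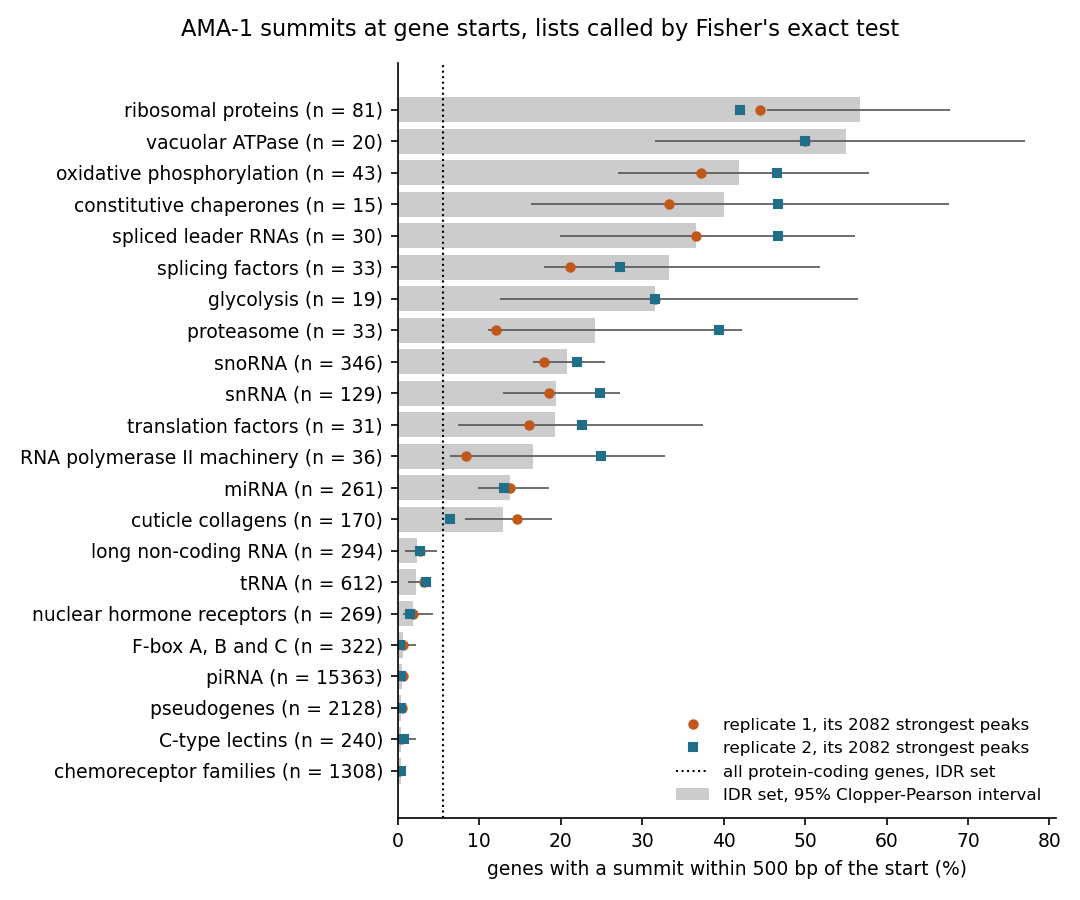
Share of each list's genes with a summit within 500 bp of the start (horizontal axis, percent), for the 22 lists called by Fisher's exact test. Bars are the IDR set with 95% Clopper-Pearson intervals, circles and squares are replicates 1 and 2, and the dotted line marks the 5.57% of all protein-coding genes; ribosomal proteins reach 56.8% and chemoreceptor families 0.382%.

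Genes for SL2 RNA, snoRNA, snRNA and microRNA had summits more often than protein-coding genes. SL2 RNA genes had one at 11 of 18 starts (61.1%), while none of the 12 SL1 RNA genes did, in the IDR set or in either replicate, which allows a share of up to 25%; together the spliced leader list stood at 36.7% (odds ratio 9.81, adjusted exact p = 1.55e-06). How reads from repeated genes were treated is not given in the sources used here, and the copies of SL1 lie in a tandem repeat. Genes for snoRNA, which guide the modification of ribosomal RNA, had a summit at 72 of 346 starts (20.8%), led by F01D5.12 (338.3), W06H8.17 (273.9) and Y55F3BR.9 (262.7). Genes for snRNA stood at 25 of 129 (19.4%), and at 14 of 99 (14.1%) without the spliced leaders, and microRNA genes at 36 of 261 (13.8%), led by mir-52, mir-4929 (231.5) and mir-54 (228.2). The summit at mir-4929 lay in a coding exon of E01G4.3, and that at mir-54 in an intron of F09A5.3. Those at F01D5.12 and Y55F3BR.9 lay in introns of F01D5.10 and Y55F3BR.2. The adjusted p from Fisher's exact test was 1.14e-20 for snoRNA, 2.81e-07 for snRNA and 3.58e-06 for microRNA genes. Many such genes lie inside or beside others; of those more than 1000 bp from any protein-coding start, 19.0% of snoRNA, 12.5% of snRNA and 15.6% of microRNA genes had a summit. That limit did not remove genes lying farther inside the body of a protein-coding gene.

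Several large families had fewer polymerase summits than other protein-coding genes, and some were nearly empty of them. Chemoreceptor families, which serve single sensory neurons, had one at 5 of 1308 starts (0.382%, adjusted p = 1.1e-25, Fisher's exact test), and the strongest of these, at srh-2, lay in a coding exon of the neighbouring icl-1; the replicates' own peaks gave 2 and 6. Pseudogenes had one at 9 of 2128 (0.423%), piRNA genes at 81 of 15363 (0.527%), C-type lectins at 1 of 240 (clec-1, 63.7), F-box genes of the A, B and C groups at 2 of 322 (fbxb-72, whose summit lay in the same peak interval as that of icl-1, and fbxb-85), nuclear hormone receptors at 5 of 269, tRNA genes at 14 of 612 and long non-coding RNA genes at 7 of 294. All 8 lists were lower than protein-coding genes (highest adjusted exact p = 0.0259, for long non-coding RNA). Against circular shifts of the IDR set, an alternative chosen after the data were seen, the lectins (adjusted permutation p = 0.203), F-box genes (0.227), nuclear hormone receptors (1), tRNA (0.555) and long non-coding RNA (0.883) were not called. The last 3 of these stood slightly above the shifts, at 1.86% against 1.80%, 2.29% against 1.71% and 2.38% against 1.99%, so they were low only beside protein-coding genes. They were also not called in replicate 1's own peaks (adjusted exact p = 0.0611, 0.227 and 0.247), among the 1041 strongest IDR peaks (0.0646, 0.0802 and 0.265) and among genes with no other protein-coding start within 1000 bp (0.0793, 0.0642 and 0.228), where fewer genes were tested and the shares were 1.62% of 247, 2.11% of 427 and 2.01% of 199. Long non-coding RNA was also not called with windows of 250 and 1000 bp or with peak intervals.

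Tissue and stage markers were mostly without an IDR summit, but so were protein-coding genes in general, of which 1113 of 19973 (5.57%) had one. A count of 0 in a short list therefore does not show a low share. In either replicate's full list, 13 of 17 molting and 40 of 47 germline genes had a peak at the start. For homeobox and P450 genes these counts were 15 of 68 and 13 of 74. On the IDR set, 19 lists were not called by Fisher's exact test. No summit was found at the starts of molting genes (0 of 17), pharynx (0 of 14), major sperm proteins (0 of 31), heat-inducible genes (0 of 9), early embryonic regulators (0 of 11), homeobox genes (0 of 68), cytochrome P450 (0 of 74), UDP-glucuronosyltransferases (0 of 67), the BATH and MATH family (0 of 73) or ribosomal RNA genes (0 of 20). With 3 genes taken as the upper limit of a count of 0, these allow shares from 4.05% (P450) to 17.6% (molting) and 33.3% (heat-inducible). Body wall muscle had 1 of 28 (act-4, 194.2), neurons 1 of 32 (snb-1), spermatogenesis 1 of 34 (spe-5), vitellogenins 1 of 6 (vit-6) and germline 2 of 47 (syp-4 and nos-3). Core histones had 6 of 72 (his-37, his-72 and his-35 highest), intestine 3 of 27 (asp-3, cpr-6, ftn-1), actins and tubulins 3 of 17 (act-4, tba-2, act-1), and glutathione S-transferases 3 of 44 (gst-7, gst-9, gst-1). The summit counted for his-35 lay in the 5′ UTR of his-41. The lowest adjusted p among the 19 was 0.0585 by Fisher's exact test, for homeobox, P450 and the BATH and MATH genes. Some of these lists passed under alternatives. Core histones were higher among genes with no other protein-coding start within 1000 bp (3 of 6 genes, adjusted exact p = 0.00444). P450 genes were lower in replicate 2's own peaks (adjusted exact p = 0.0417), with a window of 1000 bp (0.0193), with every transcript start (0.0391), with peak intervals (0.0436), over whole genes (0.0121) and in the 4164 strongest pooled peaks (0.00142). BATH and MATH genes were lower with every transcript start, over whole genes and in the pooled peaks (adjusted exact p = 0.00208). In those pooled peaks actins and tubulins were also higher (41.2%) and homeobox genes (1.47%) and UDP-glucuronosyltransferases (0%) lower. Against circular shifts, chosen after the data were seen, core histones (adjusted permutation p = 0.043), intestine (0.0194) and actins and tubulins (0.0137) were higher. The shifts place summits anywhere on a chromosome, so this sets the lists beside random positions and not beside other protein-coding genes.

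Autosomal genes carried summits more often than X-linked genes. On X, 79 of 2731 protein-coding genes (2.89%) had an IDR summit at the start, against 1034 of 17242 (5.997%) on the autosomes (odds ratio 0.467, p = 1.79e-12, Fisher's exact test, two-sided, BH-adjusted p = 4.46e-12 over 5 contrasts). In the replicates' own peaks the share was 2.58% ± 0.337 on X and 5.65% ± 1.16 on autosomes (SD, n = 2). Chromosome III was highest (8.71%), followed by I (8.20%), IV (6.46%), II (5.02%) and V (3.66%). Genes in the central part of a chromosome had summits more often than those in the outer parts, at 6.51% against 5.01% (Fisher's exact p = 9.53e-06, BH-adjusted 1.59e-05). On X alone these shares were 3.28% and 2.68% (Fisher's exact p = 0.405).

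**Figure D3:**
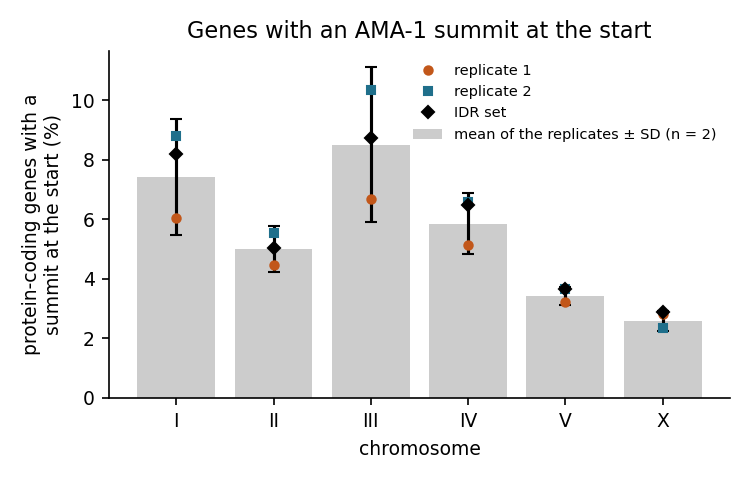
Share of protein-coding genes with a summit within 500 bp of the start (vertical axis, percent) on each chromosome. Bars are the mean of the replicates ± SD (n = 2), circles and squares the replicates, and diamonds the IDR set, which runs from 8.71% on III to 2.89% on X.

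Genes packed closely behind another gene, the arrangement found in operons, had summits near their starts more often than isolated genes. Spacing was measured between protein-coding genes only. Among 3618 genes with a same-strand neighbour that ended within 500 bp upstream, 396 (10.9%) had an IDR summit within 500 bp of the start. Of 9605 genes with no other protein-coding gene within 1000 bp upstream, 244 (2.54%) had one (odds ratio 4.72, Fisher's exact p = 2.56e-78). In the replicates' own peaks the shares were 10.6% ± 2.48 and 2.56% ± 0.00736 (SD, n = 2). The window around such a start also covers the end of the upstream gene, so a summit there belongs to both.

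The replicates shared about as many of their strongest sites as they did not within the top 100 peaks, and fewer below. Of the 2082 strongest peaks in each, 714 (34.3%) had summits within 100 bp of each other, 77.4 times the 0.443% ± 0.158 (SD) of circular shifts (permutation p = 0.001 from these shifts). The share was 49.0% for the 100 strongest peaks, 34.8% for 1000 and 31.2% for all 30000. Across 9348 matched peaks of the full lists Spearman's rho of the signal was 0.459 and Pearson's r of log10 signal 0.533. Across the 1702 IDR peaks matched in both, these were 0.0789 and 0.218. The IDR peaks were chosen by the pooled signal of both replicates, which can lower a correlation between them. The lower values therefore cannot be read as poorer agreement at strong peaks. Peaks are also not independent replicates. Among protein-coding genes, 521 had a top peak at the start in both replicates, 388 only in replicate 1 and 658 only in replicate 2, where independent lists would share 53.7.

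Some of the strongest peaks had no summit within 100 bp in the other replicate. A peak beyond the end of col-10 (V: 9163979 to 9164280) ranked 16 in replicate 1, with the nearest summit of replicate 2 at 881 bp, and the peak at the col-10 start ranked 36 and 12038. An intergenic peak at V: 4647373 to 4647521 ranked 61 in replicate 1, and the nearest in replicate 2 lay 283 bp away at rank 24652. col-140 ranked 71 and vit-6, a yolk protein gene, 176 in replicate 2, and neither had a peak within 500 bp of its start in replicate 1. Upstream of cah-4, a carbonic anhydrase, the ranks were 79 in replicate 1 and 7879 in replicate 2, whose summit lay 147 bp from the IDR summit. In the 3′ UTR of par-5, a 14-3-3 protein, the ranks were 72 in replicate 2 and 6881 in replicate 1. Distances between summits here are measured from the IDR summit. At other sites the other replicate had a strong peak nearby with its summit more than 100 bp away, as nearest summits computed after the values were seen show. In the 3′ UTR of mstr-1, near the start of kin-14, replicate 1 ranked 74 and replicate 2 ranked 26. The same was so for mak-1, in a coding exon (41 and 155) and upstream (233 and 51), and for mir-80 (81 and 57).

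Of 28 gene lists, 3 ranked higher in replicate 1 and 2 in replicate 2 when the full lists of 30000 peaks were compared by the rank percentile of the best peak at each start, a comparison chosen after the data were seen. All 40 germline genes with a peak in either list ranked higher in replicate 2, and 31 of them had a peak only there, among them pgl-3, oma-1, prg-1 and glp-1. All 13 molting genes ranked higher in replicate 1, and 10 had a peak only there, among them noah-2, myrf-1 and nhr-23. Of body wall muscle genes, 15 of 18 ranked higher in replicate 1, where unc-54 stood at percentile 94.6 and had no peak in replicate 2, and of cuticle collagens 60 of 84 did, with 24 the other way. F-box genes ranked higher in replicate 2. The median differences, replicate 1 minus replicate 2, were -51.7 points for germline, 53.4 for molting genes, 35.2 for muscle and 42.7 for collagens, against -6.67 over all 7646 genes with a peak. The permutation p, BH-adjusted over 28 lists, was 0.00014 for germline and for collagens, 0.00448 for molting genes and 0.0158 for muscle. The random draws were not matched for chromosome, and replicate 1's list held the larger share of X peaks. On X lay 7 of the 18 muscle genes, 3 of the 13 molting genes, 12 of the 84 collagens and 0 of the 40 germline genes. Ribosomal proteins (0.58 points, adjusted permutation p = 0.388) did not pass. With 1 library on each side, these tests compare the libraries and say nothing on the spread between animals.

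**Figure D4:**
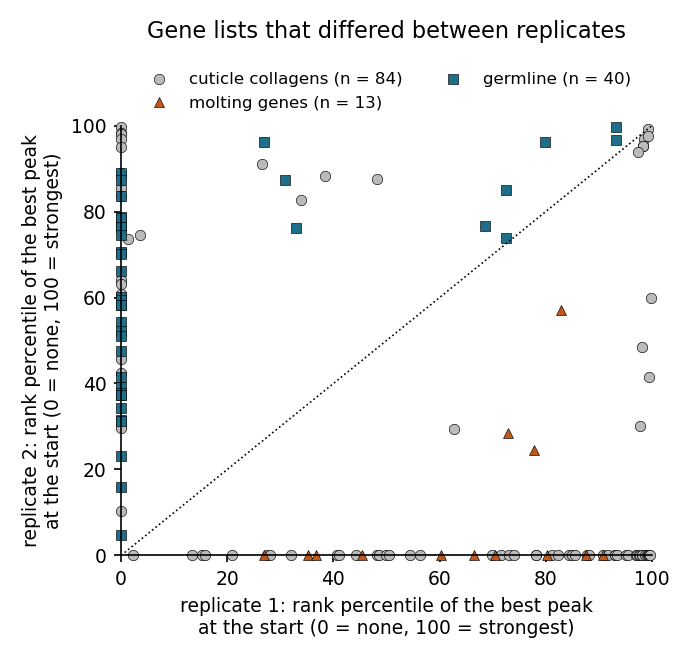
Rank percentile of the best peak within 500 bp of the start in replicate 1 (horizontal) and replicate 2 (vertical), 0 where a list has no peak there and 100 for its strongest peak; each point is a gene of the cuticle collagen, molting or germline list. All 40 germline genes lie above the dotted line of equal percentiles and all 13 molting genes below it.

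ama-1 itself, which encodes the precipitated subunit (IV: 4248070 to 4258169), had no IDR summit. Its best peak in the pooled list ranked 5901, at the start, with a signal of 28.2, and its start ranked 10335 in replicate 1 and 3581 in replicate 2.

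The same libraries were also processed on the older build ce10. The IDR set then held 2169 peaks, 87 or 4.18% more than on ce11, while each other list again held 30000. At equal rank the signal differed by a median of 0.367% in replicate 1, 0.0241% in replicate 2 and 0.00703% in the pooled list. The median width in replicate 1 was 356 bp on ce10. The share of IDR peaks per chromosome was 9.59% on X for ce10 and 9.65% for ce11.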

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

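Outside the peak set used for the comparisons, 1685 pooled peaks on ce11 carried the list's maximum −log10 q-value but were not in the IDR set. Apart from the alternative on the 4164 strongest pooled peaks, no comparison of genes used pooled peaks outside that set. Their summits lay within 500 bp of a protein-coding start in 38.6% of cases, between the 46.7% of the IDR set and the 21.9% of the other 26233 pooled peaks. A summit within 100 bp was found for 89.7% of them in replicate 1 and 81.6% in replicate 2. On ce10 there were 1596 such peaks. No explanation was tested.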

How the results depend on the processing

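All directions and calls for the X chromosome, the middle of chromosomes, closely spaced genes, the gene start share and the overlap of replicates held under each alternative tested; on ce10 the overlap was 33.9% and was not tested against shifts. Leaving out either replicate gave a gene start share of 39.2% to 50.4%, an X minus autosome difference of -4.12 to -2.01 points, a middle minus arm difference of 1.18 to 1.86 points, a closely spaced minus isolated difference of 6.29 to 9.79 points, 17 to 22 called lists and a start signal difference of 0.322 to 1.35. The number of called lists lay between 16 and 27 over all alternatives, and of the 22, 17 kept their call and direction in replicate 1's peaks, 21 in replicate 2's, 16 among the 1041 strongest peaks and 15 among genes with no other protein-coding start within 1000 bp, where fewer genes were tested. The 4164 strongest pooled peaks kept all 22 and added 5. Replicate rank correlation moved to 0.491 with summits within 50 bp and to 0.424 with intervals overlapping by 50% of each; the cause was not tested. Among the 1041 strongest peaks the signal difference of gene starts turned to -0.0469 and that of gene bodies to 2.81, neither past the threshold. These peaks were chosen by the signal compared, so this turn says nothing about stability.

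In all, 25 results for single lists or position classes turned direction and none was past the threshold on the other side. With a replicate left out these were body wall muscle (3.57% to 7.14%), intestine (3.7% to 11.1%), vitellogenins (0% to 33.3%), glutathione S-transferases (2.27% to 6.82%) and germline (4.26% to 8.51%). Among the 1041 strongest peaks they were muscle (3.57%), vitellogenins (0%), germline (4.26%) and spermatogenesis (2.94%). Germline turned with windows of 250 bp (4.26%) and 1000 bp (8.51%) and with peak intervals (6.38%), glutathione S-transferases with 1000 bp (6.82%), and muscle over whole genes (10.7%). With 4164 pooled peaks core histones (9.72%), muscle (10.7%) and glutathione S-transferases (9.09%) turned. Set against circular shifts, chosen after the data were seen, muscle (3.57%), neurons (3.12%), germline (4.26%), spermatogenesis (2.94%), nuclear hormone receptors (1.86%), tRNA (2.29%) and long non-coding RNA (2.38%) turned; the cause was not tested. No paired analysis was possible because there is 1 group.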

Other observations

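The excess of summits near gene ends came from a planned test, the other patterns weighed here were noticed in the data, and the tests of explanations were chosen after the patterns were seen. What each explanation predicts was written before the tested values were computed, but the number of collagen, molting and germline genes among each replicate's strongest peaks had been seen by then. Other groups that differed between the replicates were the F-box genes, of which 21 of 30 with a peak ranked higher in replicate 2 and 18 had a peak only there (fbxa-101, fbxc-45 and fbxc-23 highest among these); their median difference was -38.05 points (BH-adjusted permutation p = 0.0158 over 28 lists). Nuclear hormone receptors leaned to replicate 1, with 49 of 82 higher there, and did not pass (7.32 points, adjusted permutation p = 0.0523). Proteasome genes ranked higher in replicate 2 for 26 of 32 (adjusted permutation p = 0.443). Over all genes, 4307 had a peak at the start in both lists of 30000, 1279 only in replicate 1 and 2060 only in replicate 2.

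Cuticle collagen starts were called more often in replicate 1: 19 collagens were called there only and 5 in replicate 2 only, against 369 and 653 other genes (odds ratio 6.72, Fisher's exact p = 3.87e-05). GC content of the gene start argues little for it, since the odds ratio pooled over 5 GC strata stayed at 5.40 (95% interval 1.98 to 14.8), though 20 of the 24 collagens fell in the highest stratum; over gene length strata it was 7.996 (2.86 to 22.3). The difference was also present over all 30000 peaks of each list, with a median of 42.7 points. This cannot exclude a limit on rank, because those lists are cut by rank too and an absent gene was scored 0. Of the 84 collagens with a peak in either list, 49 had one only in replicate 1 and 18 only in replicate 2. A candidate explanation is that the animals of the replicates were at different points of the molting cycle, as the molting genes, a separate list, differed by 53.4 points in the same direction, 13 of 13. Body wall muscle (35.2 points) and germline genes (-51.7 points) moved too. A larger share of signal from soma over germline in replicate 1, or a difference in age or culture, therefore stays open as well. A larger somatic share alone would not account for the 24 of 84 collagens that ranked higher in replicate 2. Other somatic lists did not pass. Intestine differed by 3.36 points (8 of 16 higher in replicate 1, adjusted permutation p = 0.522) and neurons by 8.92 (10 of 13, 0.443).

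Replicate 1's full list held more X chromosome peaks, 14.5% against 8.78%. Weak, background-like peaks are not the whole cause: the difference was 5.29 points among the 10000 weakest (95% interval 4.41 to 6.17) and 5.58 among the 5000 strongest (4.37 to 6.79). Less germline signal in replicate 1 may account for part of it, since X is known to hold few germline-expressed genes and the germline list's median difference was -51.7 points, with 40 of 40 genes lower in replicate 1. That link to X itself was not tested, and for spermatogenesis genes the difference did not pass (-5.64 points, 9 genes, adjusted permutation p = 0.978). Whether replicate 2 held more germline tissue or older animals cannot be read from the peak lists.

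IDR summits near gene ends exceeded the circular shifts, at 1198 of 19973 ends, 2.999 times the shifts. Starts of neighbouring genes are not the whole cause: at the 10957 ends with no other gene start within 1000 bp, 509 had a summit, 2.35 times the shifts (permutation p = 0.001, the smallest that 1000 shifts can give). Short genes are not the whole cause either, as the ratio was 3.16 for genes over 2000 bp, and with both conditions 297 of 5861 ends had a summit (5.07% against 1.98%, a ratio of 2.56). The number was alike in the replicates, 315 and 287. No biological explanation was tested.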
